A study of Homo sapiens with 5 samples.

How the data were processed

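RNA-seq and ribosome profiling (Ribo-seq, sequencing of mRNA fragments protected by ribosomes, called footprints below) were done in HEK293A cells, an adherent derivative of the human embryonic kidney line HEK293. The cells received a control siRNA (siCon) or an siRNA against IRE1α (siIRE1a), an endoplasmic reticulum stress sensor encoded by ERN1, and were starved and then given fetal bovine serum. The 5 samples were 2 siCon libraries, 2 siIRE1a libraries and 1 Ribo-seq library in which all cultures were multiplexed. The descriptions call the siCon samples RNA-seq and the siIRE1a samples Ribo-seq, which conflicts with the multiplexed sample and with the tables, where both groups have values for both assays. Groups were therefore taken from the siRNA labels and assays from the column names of the tables.

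A sequencing run summary deposited with the series gave, for the 4 titled libraries, the count of clusters that passed the instrument filter, the yield in megabases and a mean base quality score per the file headers. Nothing in it identifies the multiplexed library, and how many reads stand behind each abundance value is unknown. The deposited abundance table held 1 footprint value and 1 RNA value per group and gene. Its unit is not stated. The values were positive and fell with coding length, as length-normalized abundances do. The authors' TE (translational efficiency) columns were the ratio of footprint to RNA abundance of the same group, to within rounding error. The deposited comparison table held a log2 change in TE and an adjusted p-value for each gene, and the authors named it after DESeq2. The model, the counting of reads, the combination of replicates and the method of adjustment were not stated, nor whether the replicates were separate cultures. The sign of the authors' log2 change matched siIRE1a over siCon in the ratio of the TE columns for all 934 genes called below. The submitters' processing notes named the hg19 (GRCh37) genome and Bowtie 1.1.2. No coordinates were given for the genes.

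Each table had 10522 entries. The 9 symbols with 2 entries each were left out, which left 10504 genes, 8878 of them with an adjusted p-value and 1626 without. A further 17 symbols had been turned into dates and were kept but not named. Changes in RNA and footprints were computed as log2 of the siIRE1a value over the siCon value. A pseudocount of 1 had been chosen before the data were examined. It was replaced by none, since no value was 0 and most RNA values lay under 1, and pseudocounts of 0.1, 1 and 5 became alternatives. Genes at least 2-fold apart were counted among genes with a mean abundance of at least 1 in that assay (2159 genes for RNA, 7033 for footprints).

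With 1 value per group and assay, no spread between replicates could be estimated, so RNA and footprint changes are values with no test. The planned edgeR and limma models, the camera and fry list tests and the replicate analyses could not be run. For TE, a gene was called higher or lower at a deposited adjusted p under 0.05. Standard errors of the authors' log2 changes were back-calculated on the assumption of a two-sided normal test and the Benjamini-Hochberg adjustment. Where the back-calculated p was 0.5 or more, the median of genes of like abundance was used.

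The 23 gene lists and the rule for naming genes were fixed before the data were examined. For each of the 22 lists with at least 5 measured genes, the median change in RNA and in footprints was set against 10000 random lists matched on abundance in 20 bins, and is given as a percentile of these. A second set of random lists was matched on GC content and abundance. Called genes were compared between the list and all other tested genes with a two-sided Fisher's exact test for each direction, and the 44 p-values were adjusted together by Benjamini-Hochberg. That test and the random lists treat genes as independent, which overstates the evidence where members vary together. The rule named ERN1 and XBP1, the 10 genes with the largest rise and the 10 with the largest fall in each comparison, and up to 4 members per list with the smallest p. For TE it was applied to called genes of the authors' table. Some genes that the rule takes are counted but not reported here by name. For RNA and footprints, which have no test, it was applied to genes with a mean abundance of at least 1.

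Transcript GC content (both UTRs and the coding sequence) and 3′ UTR sequences came from GENCODE release 29, matched by symbol for 10452 genes (99.5%), 263 of them through an older symbol. A trend of the TE change on GC content was fitted as a polynomial of degree 3, and the change minus the trend was tested again with the back-calculated standard errors. All 16384 7-mers were scanned against the footprint changes of the 10238 genes with a 3′ UTR of at least 50 bases, as a search for targets of an siRNA seed. Intervals of medians are 95% bootstrap intervals over genes. The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

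The procedures were tested on simulated data. With TE changes simulated for 8835 genes at the back-calculated standard errors, 44% of genes changed 1.5-fold and 85% of genes changed 2-fold were called, together with 10 of 8635 unchanged genes. The GC trend fitted here, left in the simulated values, led to 615 unchanged genes being called, and its removal brought that number to 12. The same kind of polynomial was used for removal, with the standard errors of the simulation. Trends of another shape and errors in the standard errors were therefore not tested. Of 200 random lists of 25 genes, 4.5% fell outside the middle 95% of the matched lists, and 82% were found in the lowest 5% once their footprint values had been lowered by 0.1. Lists whose members vary together were not simulated. All 20 planted 7-mers ranked first in the scan.

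The alternatives tried were other pseudocounts, other abundance filters, median centring and quantile normalization of the changes, other thresholds, and the omission of ribosomal protein and mitochondrially encoded genes. Removal of the GC trend, omission of genes with a seed 7-mer in the 3′ UTR and repeated adjustment of the back-calculated p were chosen after seeing the data.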

Results

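Protein synthesis was induced in starved HEK293A cells by fetal bovine serum, with or without depletion of IRE1α, and RNA and ribosome footprints were compared between the siRNA groups. There were 2 siCon and 2 siIRE1a libraries and 1 multiplexed Ribo-seq library. The siCon libraries had 28769136 and 31876615 clusters and the siIRE1a libraries had 49112701 and 34172898, with mean base quality scores between 35.86 and 36.03. Abundances of 10504 genes were given as 1 value per group and assay, so no replicate error can stand beside an RNA or footprint value. All changes below are siIRE1a relative to siCon.

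The first question was whether the siRNA target itself was lower. ERN1 RNA abundance was 0.121 in siCon and 0.0736 in siIRE1a cells, which was 1.65-fold lower (log2 −0.72). Its footprint abundance was 1.46-fold lower, at 0.402 and 0.275 (log2 −0.55). These are low values, and a pseudocount of 0.1 reduced the RNA change to −0.35 while a pseudocount of 1 reduced the footprint change to −0.14. The TE of ERN1 did not pass the test, with a log2 change of 0.14 (adjusted p = 0.807) in the authors' deposited table. XBP1, whose mRNA is spliced by IRE1α, had RNA values of 1.19 and 1.15 and footprint values of 4.16 and 3.83. Its TE change in the authors' deposited table was −0.05 (adjusted p = 0.912). The tables hold 1 value per gene and so do not separate spliced from unspliced XBP1.

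The second comparison asked what IRE1α depletion changed in RNA abundance. The largest increase was in TRIM43, a member of a primate gene family of tripartite motif proteins, from 0.489 to 2.31 (4.72-fold). PNP, the purine nucleoside phosphorylase of purine salvage, was 2.98-fold higher, the intermediate filament keratin KRT17 2.88-fold, DHRS2 2.16-fold and FN1 (fibronectin) 1.93-fold. PLXNB2, a semaphorin receptor, and ATPIF1, an inhibitor of the mitochondrial ATP synthase, were both 1.87-fold higher. FBLN1 (fibulin) and the linker histone gene HIST1H1D were both 1.85-fold higher, and SERPINH1, the collagen chaperone of the endoplasmic reticulum, 1.81-fold. ZMAT2, a zinc finger gene, was 3.02-fold lower, from 2.38 to 0.787. HEY1, a transcriptional repressor downstream of Notch, was 2.39-fold lower, C16orf87 2.38-fold and the COPII coat gene SEC23A 2.25-fold. The start codon selection factor EIF1AX went from 12.0 to 5.42, which was 2.21-fold lower. AZIN1 (antizyme inhibitor) was 2.16-fold lower, RDH14 (a retinol dehydrogenase) 2.15-fold and GTF3C6 (a subunit of transcription factor TFIIIC) 2.13-fold. MT-ND6, a complex I subunit encoded on the mitochondrial strand opposite to MT-ND5, was 2.25-fold lower. Changes of at least 2-fold were few: among 2159 genes with a mean RNA abundance of at least 1, 4 were at least 2-fold higher and 11 at least 2-fold lower, and 90.5% lay within 1.5-fold. Without the abundance filter these counts were 36 and 49, and with a minimum of 10 they were 0 and 1.

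RNA changes followed the base composition of the transcript. Across 10452 genes, which are not independent replicates, Spearman's rho between RNA change and GC content was 0.626 (Pearson's r = 0.583). When genes were split into 5 groups of equal size by GC content, the median RNA change was −0.37 at a median GC content of 38.7% and 0.22 at 61.5%. The 10 genes taken by the rule with higher RNA had a median GC content of 54.3% and the 10 with lower RNA 42.5%, against 47.9% for all genes. The RNA medians of the lists below are therefore also set against random lists matched on GC content.

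Higher RNA medians were seen for serum immediate-early genes, SRF targets, secreted and matrix proteins and histones. No group without serum was measured, so these values do not show a response to serum. The 21 measured serum immediate-early genes had a median RNA change of 0.37, above all 10000 random lists (percentile 99.99 with GC matching), and 18 of them were above 0. Among them, the phosphatase gene DUSP1 changed by 0.70, CTGF and CYR61, encoding secreted growth regulators, by 0.65 and 0.74, and JUN by 0.46. The 15 cytoskeletal targets of the serum response factor SRF had a median of 0.44 (percentile 100, and 99.98 with GC matching), with FLNA (filamin) at 0.62 and ACTG1 (actin) at 0.34. The 31 secreted and matrix proteins had a median of 0.35 (percentile 100 both ways), and 27 were above 0. Replication-dependent histones, whose mRNAs end without a poly(A) tail, had a median of 0.35 over 14 genes (percentile 99.98, and 99.6 with GC matching). How fully the RNA values cover such mRNAs was not tested.

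Lower RNA medians were seen for ER translocation and glycosylation, the machinery that moves proteins into the endoplasmic reticulum (−0.24 over 30 genes, percentile 0.61), and for mitotic cell cycle genes (−0.25 over 25 genes, percentile 1.05). With GC matching these were at percentiles of 6.14 and 11.0. Ribosome biogenesis genes had a median of −0.17 over 27 genes (percentile 6.87, and 0.14 with GC matching). The p53 targets had a median of 0.15 over 18 genes (percentile 97.1, and 98.9 with GC matching), which became 0.40 over members with a mean of at least 1, and 13 were above 0 and 5 below. The 4 members taken by the rule were among those below 0: RRM2B (−0.72), PMAIP1 (−0.44), TP53INP1 (−0.28) and ZMAT3 (−0.19). ATF4 and CHOP targets had a median of 0.19 over 23 genes (percentile 98.6, and 91.2 with GC matching).

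Among targets of the unfolded protein response, the 23 XBP1s targets had a median RNA change of −0.03 (percentile 46.7, and 46.4 with GC matching), with 10 members above 0, and the sign of that median turned under quantile normalization. The 13 ATF6 targets had a median of 0.16 (percentile 93.8, and 97.9 with GC matching), which became −0.11 over members with a mean of at least 1. The 10 substrates of RIDD, the decay of mRNAs cleaved by IRE1α, had a median of 0.17 (percentile 96.9, and 86.1 with GC matching), which became 0.085 over members with a mean of at least 1. Interferon-stimulated genes were at 0.16 over 12 genes (percentile 86.6, and 92.8 with GC matching). Stress mRNAs controlled by upstream open reading frames were at −0.17 over 8 genes (percentile 23.5, and 11.9 with GC matching), which became 0.22 over members with a mean of at least 1. Cytosolic ribosomal proteins (0.05 over 77 genes), other TOP mRNAs (−0.11 over 21), initiation factors (0.04 over 33), cholesterol biosynthesis (0.02 over 22), nuclear-encoded OXPHOS (0.01 over 39), mitochondrially encoded genes (−0.09 over 13), DNA replication (−0.04 over 30) and heat shock and chaperones (−0.12 over 20) lay between percentiles 17.7 and 80.8. With GC matching these lay between percentiles 27.3 and 95.4, the highest being initiation factors (95.4) and mitochondrially encoded genes (89.1), and other TOP mRNAs were at 70.2. None of the 14 blood and liver cell markers was among the measured genes.

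The third comparison concerned the abundance of ribosome footprints after serum, which is not divided by the RNA of the gene. The 7 measured genes TRIM43, TRIM48, TRIM49, TRIM49B, TRIM49C, TRIM49D1 and TRIM49D2 had footprints between 3.28-fold and 4.24-fold higher in siIRE1a cells, and their RNA was higher as well (log2 1.21 to 2.24). These genes are close paralogs and are not counted as 7 separate observations. TRIM49D1 and TRIM49D2 had equal footprint values, equal RNA changes (log2 1.66) and equal TE changes in the authors' deposited table (0.063), so this pair is 1 observation. Whether the other paralogs share reads was not tested. THBS1, the matrix glycoprotein thrombospondin, went from 1.13 to 3.13 (2.76-fold), PNP from 15.5 to 35.3 (2.28-fold) and KRT17 from 9.57 to 20.8 (2.17-fold). The largest decrease was in NDUFA7, a complex I subunit, from 21.3 to 7.40 (2.88-fold lower). TRMT10A, a tRNA methyltransferase, was 2.69-fold lower, CDK2AP2 2.54-fold, CHCHD4, which imports proteins into the mitochondrial intermembrane space, 2.43-fold, and the transcription factor gene E2F5 2.36-fold. ZMAT2 footprints were 2.34-fold lower, AGTRAP 2.31-fold, the retinol dehydrogenase gene RDH10 2.22-fold and TTLL12 1.94-fold. Footprints of LARS, the leucyl-tRNA synthetase, went from 4.32 to 2.16. Of these 10 genes, all but E2F5 had a 3′ UTR with GGACCTA or GACCTAA. These 7-mers had the lowest footprint changes in a scan of these same values, so that count is partly set by their choice. None of the 10 named genes with higher footprints had one, but 7 of those are the TRIM paralogs above. Large changes were rare in footprints. Of 7033 genes with a mean of at least 1, 10 were at least 2-fold higher, among them the 7 TRIM paralogs, and 8 at least 2-fold lower. Within 1.5-fold lay 98.7%. Without genes that carry either 7-mer, 1 gene was at least 2-fold lower.

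**Figure D1:**
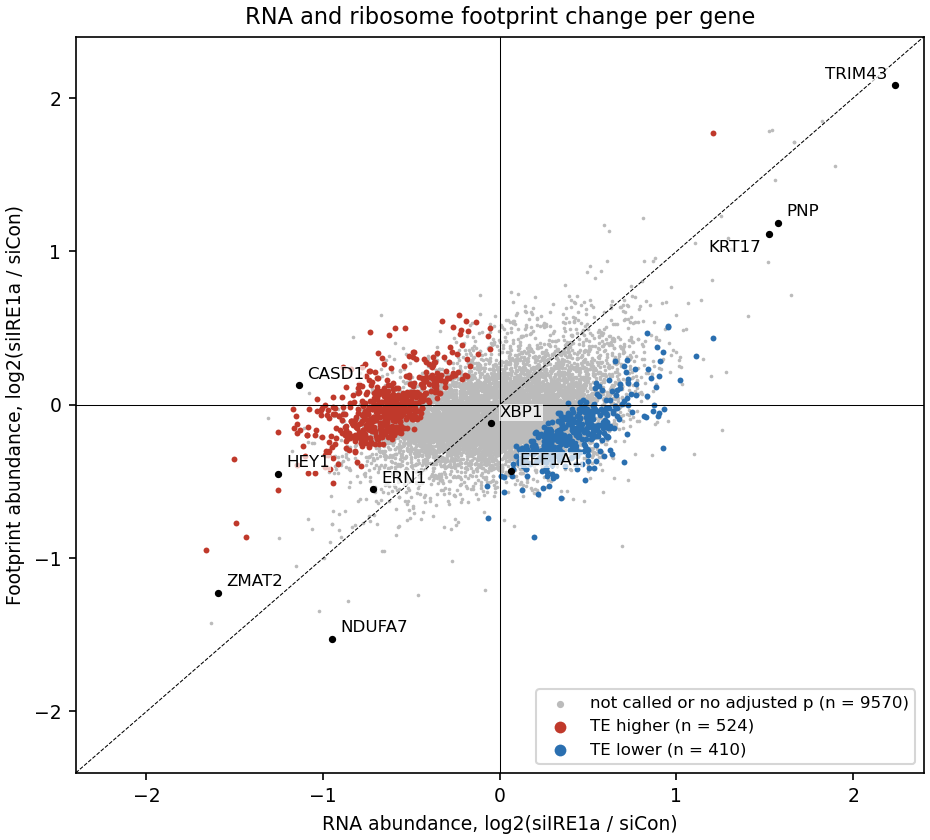
RNA change (horizontal, log2 of siIRE1a over siCon) against footprint change (vertical, log2) for 10504 genes, 1 point per gene. Genes called in the authors' table with higher TE (524) or lower TE (410) are coloured, the dashed line marks equal change, and 10 genes are named, with TRIM43 at the upper right.

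All 77 cytosolic ribosomal protein genes had lower footprints in siIRE1a cells, with a median change of −0.34, below all 10000 random lists of like abundance and against −0.08 for all genes. Random lists matched on footprint abundance and coding length had a median of −0.19. After quantile normalization, which gives both groups the same distribution of values, their median was −0.09 against −0.01 for all genes and still below all random lists. Footprints of RPL24 went from 214 to 170 and those of RPL19 from 171 to 139. Other TOP mRNAs, which share the 5′ terminal oligopyrimidine motif of ribosomal protein mRNAs, had a median of −0.25 over 21 genes (percentile 0.40), and 20 were below 0. EEF1A1, the elongation factor that delivers aminoacyl-tRNA, went from 611 to 453, and EEF2, the translocation factor, from 119 to 97.9. All 27 ribosome biogenesis genes were below 0 with a median of −0.26 (percentile 0), and NOP56, a core protein of box C/D small nucleolar ribonucleoproteins, went from 12.6 to 9.44. Translation initiation factors had a median of −0.18 over 33 genes (percentile 2.84, within the middle 95% of random lists), with 32 below 0. With GC matching they were at percentile 3.01, and after quantile normalization at 0.44, outside the middle 95%.

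Mitotic cell cycle genes had a median footprint change of −0.20 (percentile 0.12), with 24 of 25 below 0, and the 4 members taken by the rule lay between −0.10 (KIF11) and −0.75 (AURKB). DNA replication genes were at −0.18 (percentile 2.01), and all 30 were below 0, though with GC matching (percentile 2.76) and after quantile normalization (2.74) the list lay within the middle 95% of random lists. Nuclear-encoded OXPHOS genes (−0.19 over 39 genes, percentile 4.63) and histones (−0.25 over 14 genes, percentile 3.17) lay within the middle 95% of random lists matched on abundance and outside it with GC matching (percentiles 2.34 and 0.35). Quantile normalization moved these positions to 0.51 for OXPHOS genes and 73.0 for histones.

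Serum immediate-early genes had a median footprint change of 0.14 (percentile 100), with 17 of 21 above 0, and DUSP1 went from 19.0 to 22.6. Secreted and matrix proteins were at 0.10 over 31 genes (percentile 100), and 24 were above 0. ATF6 targets were at 0.09 (percentile 99.99), with 11 of 13 above 0. Of that list, the chaperone gene CANX (calnexin) went from 49.2 to 47.9 in footprints and from 11.8 to 8.52 in RNA, and HSP90B1 from 63.5 to 73.5 in footprints and from 13.3 to 11.3 in RNA. RIDD substrates were at 0.14 (percentile 99.99), with 9 of 10 above 0, and CD59, which encodes a complement inhibitor, went from 21.1 to 22.1. The p53 targets were at 0.09 (percentile 100), with 15 of 18 above 0. ATF4 and CHOP targets were at 0.02 over 23 genes (percentile 99.7). Relative to the median of all genes, XBP1s targets (−0.03, percentile 98.3), ER translocation genes (−0.07, percentile 98.8) and mitochondrially encoded genes (−0.02, percentile 99.8) also lay high, and their medians turned positive under median centring. SRF cytoskeletal genes (−0.04, percentile 92.9) turned positive in the same way. Interferon-stimulated genes were at 0.08 (percentile 98.8), or 0.0047 over members with a mean of at least 1, uORF-controlled stress mRNAs at 0.03 (percentile 93.8), cholesterol biosynthesis at −0.13 (percentile 21.4) and heat shock and chaperones at −0.15 (percentile 47.3).

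**Figure D2:**
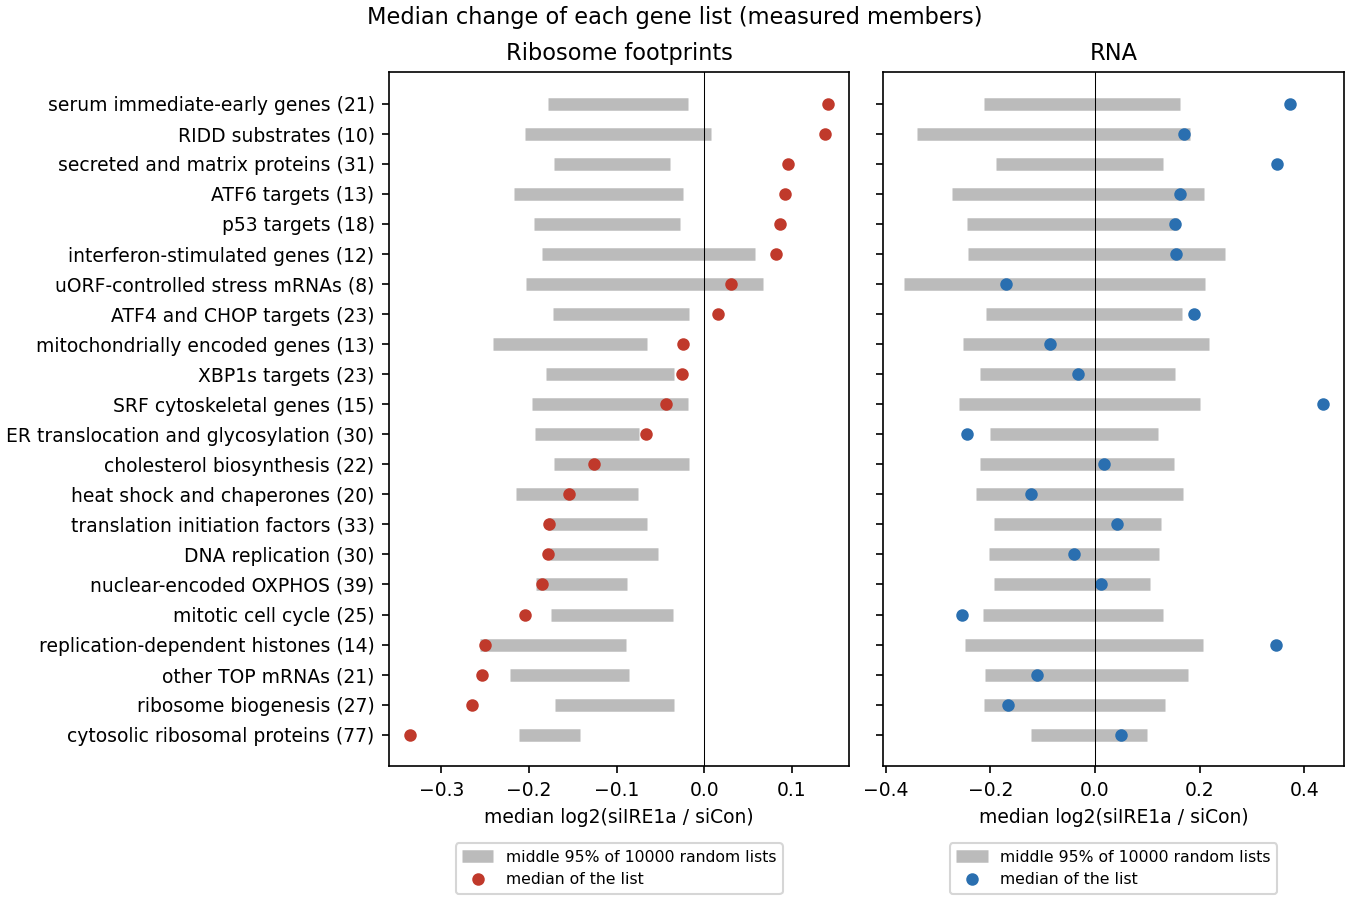
Median log2 change of siIRE1a over siCon in footprints (left) and RNA (right) for 22 gene lists, with the number of measured genes in brackets. Grey bars span the middle 95% of 10000 random lists matched on abundance; the ribosomal protein list lies at −0.34 in footprints and 0.05 in RNA.

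The fourth comparison, of TE, rests on the authors' test. The authors' deposited table had 934 genes at an adjusted p under 0.05 among 8878, of which 524 rose and 410 fell. A back-calculated p under 0.05 was found for 2295 genes (25.9%). Changes were modest, with a median fold of 1.52 among called genes and 26 genes at an absolute log2 change of at least 1. Genes whose TE rose had a median RNA change of −0.64 and a median footprint change of −0.03, and in 505 of them (96.4%) RNA had moved further than footprints. Genes whose TE fell had medians of 0.40 in RNA and −0.20 in footprints, and RNA had moved further in 306 (74.6%). The median back-calculated standard error was 0.196.

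Among the largest rises in the authors' deposited table were those of CASD1, a sialic acid acetyltransferase (log2 1.28, adjusted p = 3.7e-04) and CARNMT1, the carnosine methyltransferase (1.16, adjusted p = 1.0e-04). They were followed in the authors' deposited table by NXT2, an mRNA export factor (1.16), MT-ND6 (1.12), the nucleotidase gene NT5C3A (1.12), the sterol sensor gene INSIG2 (1.09), C16orf87 (1.09), HINT3 (1.09) and C21orf91 (1.08), with adjusted p between 6.9e-05 and 0.0317. INSIG2 RNA went from 0.287 to 0.190 and its footprints from 1.59 to 2.25. The largest falls in the authors' deposited table were in the histone gene HIST1H3J (log2 −1.19, adjusted p = 0.00775), ZNF827 (−1.03, adjusted p = 0.0103) and RPL36A-HNRNPH2, a readthrough gene that overlaps RPL36A (−1.02, adjusted p = 6.3e-06). ABHD11 (−0.97), ZNF324 (−0.95), the formin gene INF2 (−0.93) and the adaptor subunit gene AP1G2 (−0.92) followed in the authors' deposited table with adjusted p between 0.0109 and 0.0398. The ribosomal protein gene RPL24 also fell in the authors' deposited table (−0.91, adjusted p = 2.3e-11). Back-calculated standard errors were 0.274 for CASD1, 0.323 for HIST1H3J and 0.115 for RPL24.

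TE calls separated by GC content. The 10 rises taken by the rule had a median GC content of 37.1% and the 10 falls 58.6%. In the group of genes with the lowest GC content, 360 of 1848 tested genes rose and 0 fell, while in the group with the highest, 4 of 1619 rose and 169 fell. Footprint change had a Spearman's rho of −0.043 with GC content across genes, and TE change one of −0.673. With the GC trend removed, an alternative chosen after seeing the data, 50 genes rose and 59 fell among 8835. Of these, 79 had been called before with the same sign, 850 earlier calls were lost, and the median absolute log2 change of the earlier calls went from 0.60 to 0.33. Median centring of the TE change gave 630 rises and 308 falls, so that 67.2% of calls were rises in place of 56.1%. Of the 10 largest rises and 10 largest falls, 1 and 3 kept an adjusted p under 0.05 with the trend removed, among them C16orf87 (0.00948), RPL24 (1.8e-11) and RPL36A-HNRNPH2 (4.2e-05). Calls that were lost included CASD1 (0.0675), CARNMT1 (0.0861), NXT2 (0.467), MT-ND6 (0.247), INSIG2 (0.271), HIST1H3J (0.140) and ZNF827 (0.124). In that order, their log2 TE changes with the trend removed were 0.90, 0.72, 0.60, 0.92, 0.64, −0.93 and −0.85.

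**Figure D3:**
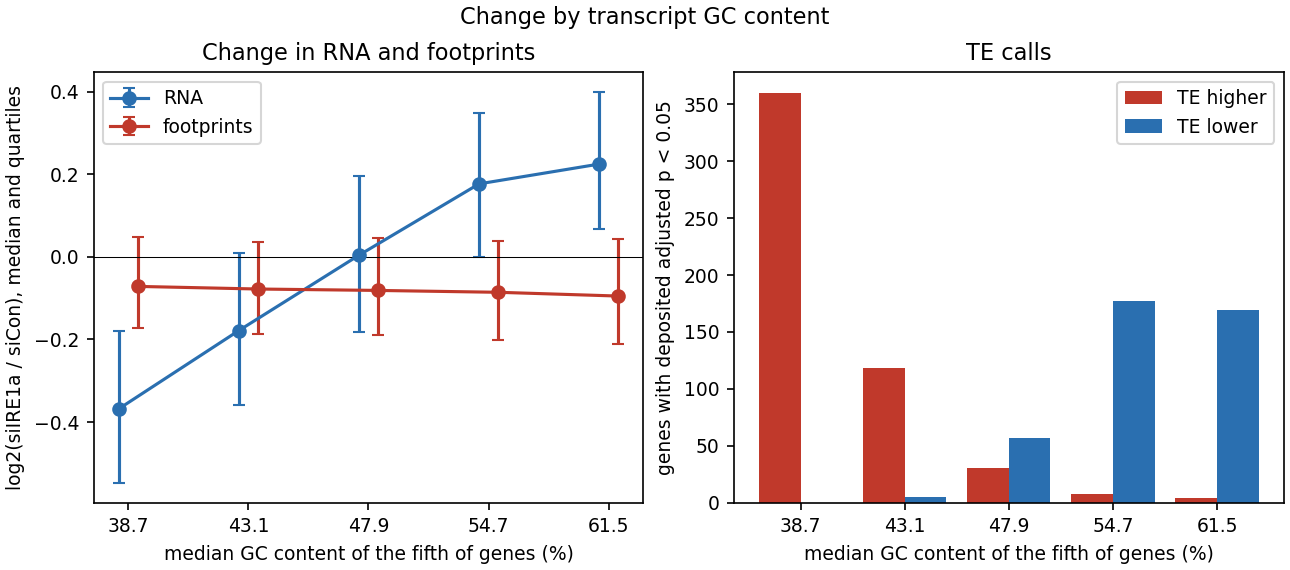
Left, median log2 change of siIRE1a over siCon in RNA and footprints, with bars from the lower to the upper quartile, for 5 groups of genes ordered by transcript GC content (horizontal, median GC in percent). Right, the number of genes per group with higher or lower TE in the authors' table, from 360 and 0 in the first group to 4 and 169 in the last.

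TE of many ribosomal protein genes fell. In the authors' deposited table, 31 of 77 cytosolic ribosomal protein genes fell and 0 rose, and 44 fell when adjusted over the list alone. The share that fell was 9.35 times that of the other genes (Fisher's exact adjusted p = 2.6e-20), and with the GC trend removed 20 fell (Fisher's exact adjusted p = 4.2e-26). RPL19 (log2 −0.70, adjusted p = 1.5e-06) and RPS15 (−0.73, adjusted p = 3.2e-06) in the authors' deposited table were examples beside RPL24. Of 21 other TOP mRNAs, 7 fell and 2 rose, with 8 and 3 adjusted over the list alone (Fisher's exact adjusted p for falls = 4.1e-04, and 2.2e-04 with the GC trend removed). The median TE change of these 21 genes was −0.11 in the authors' deposited table (percentile 48.5, and 3.01 with GC matching). The calls included, in the authors' deposited table, EEF2 (−0.70, adjusted p = 1.1e-04), EIF3L (−0.55, adjusted p = 0.00155), EEF1A1 (−0.49, adjusted p = 0.00192) and EEF1D (−0.55, adjusted p = 0.00333). With the GC trend removed EIF3L and EEF1A1 kept an adjusted p under 0.05, and EEF2 (0.0829) and EEF1D (0.345) did not.

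TE of 10 of 14 replication-dependent histones fell and 1 rose, with 11 and 1 adjusted over the list alone (Fisher's exact adjusted p for falls = 7.4e-10). Examples in the authors' deposited table were HIST1H1C (−0.64, adjusted p = 2.0e-04) and HIST1H3H (−0.81, adjusted p = 2.2e-04), of which HIST1H3H kept its call with the GC trend removed and HIST1H1C did not (0.0934). With the GC trend removed, 2 histones fell (Fisher's exact adjusted p = 0.0556), while the median TE change of the list went from −0.59 in the authors' deposited table to −0.37. The first of these medians was below all random lists, with and without GC matching. In siCon cells HIST1H3H had an RNA value of 1.68 and a footprint value of 208, and HIST1H1C 40.1 and 458. How fully the RNA values cover mRNAs without a poly(A) tail was not tested, which limits the RNA and TE changes of histones. In ER translocation and glycosylation, 8 of 30 genes rose and 3 fell, with 12 and 6 adjusted over the list alone (Fisher's exact adjusted p for rises = 0.00283, and 0.986 with the GC trend removed). The median TE change was 0.26 in the authors' deposited table (percentile 99.99, and 99.96 with GC matching) and 0.11 with the GC trend removed. The translocon-associated genes TRAM1 (0.75, adjusted p = 8.5e-05), SEC62 (0.72, adjusted p = 0.00175) and SEC63 (0.70, adjusted p = 0.00333) and the signal recognition particle gene SRP9 (0.59, adjusted p = 3.7e-04) rose in the authors' deposited table, and their GC content lay between 35.7% and 39.4%. None of these 4 kept its call with the GC trend removed. Of 30 secreted and matrix proteins, 7 fell and 0 rose, with 8 and 0 adjusted over the list alone (Fisher's exact adjusted p for falls = 0.00302, and 1 with the GC trend removed), among them SERPINH1 (−0.68, adjusted p = 4.3e-04), TIMP1 (−0.50, adjusted p = 0.0169) and FN1 (−0.43, adjusted p = 0.0260) in the authors' deposited table. Of 13 SRF cytoskeletal genes, 4 fell and 0 rose, the same counts adjusted over the list alone (Fisher's exact adjusted p for falls = 0.0168, and 1 with the GC trend removed). In the authors' deposited table these were FLNA (−0.65, adjusted p = 0.00266), MYH9 (−0.50, adjusted p = 0.0106), MYL9 (−0.79, adjusted p = 0.0365) and ACTG1 (−0.40, adjusted p = 0.0473). The median TE changes of secreted and matrix proteins and of SRF genes were −0.23 and −0.40 in the authors' deposited table (percentiles 1.05 and 0.05, and 35.0 and 2.27 with GC matching), and −0.10 and −0.16 with the GC trend removed. Median centring ended the call for SRF genes (Fisher's exact adjusted p = 0.0670) and for secreted and matrix proteins (Fisher's exact adjusted p = 0.120).

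For the remaining lists neither direction passed Fisher's exact test after adjustment. Of the unfolded protein response lists, 1 of 23 XBP1s targets rose (SSR1, log2 0.48) and 1 fell (SEC61A1, −0.47) in the authors' deposited table. Of 13 ATF6 targets, CANX (0.45, adjusted p = 0.00971) and HSP90B1 (0.49, adjusted p = 0.0294) rose and 0 fell in the authors' deposited table. Of 10 RIDD substrates, CD59 rose (0.63, adjusted p = 9.6e-04) and COL6A1 fell (−0.43, adjusted p = 0.0398) in the authors' deposited table. With the GC trend removed CD59 kept its call (adjusted p = 0.0192), and SSR1 (0.665), SEC61A1 (0.491), CANX (0.573), HSP90B1 (0.532) and COL6A1 (0.742) did not. None of 21 tested ATF4 and CHOP targets and none of 8 uORF-controlled stress mRNAs was called, the lowest adjusted p in the authors' deposited table being that of PPP1R15A (0.0630), which is in both lists. The uORF-controlled mRNAs had a median TE change of 0.26 in the authors' deposited table (percentile 97, and 98.85 with GC matching), with 7 above 0. With the GC trend removed 1 of them, ATF5, was called higher (adjusted p = 0.0494). Rises and falls numbered 3 and 3 of 33 initiation factors, 1 and 4 of 27 ribosome biogenesis genes, 0 and 2 of 19 serum immediate-early genes, 1 and 2 of 19 cholesterol biosynthesis genes, and 1 and 4 of 39 OXPHOS genes. They numbered 3 and 0 of 13 mitochondrially encoded genes, 1 and 1 of 24 mitotic genes, 1 and 3 of 30 DNA replication genes, 0 and 1 of 6 interferon-stimulated genes, 4 and 3 of 17 p53 targets and 1 and 3 of 20 heat shock genes and chaperones. Adjusted over the list alone, the counts differed for initiation factors (4 and 4), p53 targets (5 and 4), heat shock genes (1 and 4) and ATF6 targets (2 and 1). EIF1AX had the strongest single call among these lists in the authors' deposited table (0.98, adjusted p = 5.0e-08), at a GC content of 35.1%, and with the GC trend removed its change was 0.44 (adjusted p = 0.105).

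Over all genes, relative values of this kind cannot show a global rise or fall in translation, since the median is set by the scaling. Among 2123 genes with a mean of at least 1 in both assays, the median change was −0.03 in RNA, −0.13 in footprints and −0.10 in TE, and the SD across genes was 0.354, 0.180 and 0.331. RNA and footprint changes had a Pearson's r of 0.379 and a Spearman's rho of 0.262 across these genes, which are not independent replicates. The change in TE had a Pearson's r of −0.865 with the change in RNA, a value from which it is computed.

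Genes whose 3′ UTR held GGACCTA or GACCTAA had lower footprints and lower RNA. These 7-mers were picked as the lowest in the scan of these same footprint changes. The footprint differences and the share of genes with a site below are therefore partly set by that choice. The 158 genes with the 8-mer GGACCTAA had a median footprint change of −0.17 (95% interval −0.22 to −0.13) and a median RNA change of −0.27 (95% interval −0.36 to −0.17). The 770 genes with a 7-mer only had medians of −0.13 and −0.21, and the 9310 genes with neither had −0.08 and 0.00. Of the 50 genes with the lowest footprint change among 6853 with a mean of at least 1, 36 (72%) had a site, against 9.02% of all of these. In the scan by RNA change GGACCTA ranked 4633 from the lowest, and 1 after the trends with GC content and UTR length were removed. ERN1 had neither 7-mer in its 3′ UTR and each of them once in its coding sequence. On the minus strand of chromosome 17 (GRCh38), GGACCTA was at 64044906 to 64044912 in exon 21 of 22, and GACCTAA at 64052965 to 64052971 in exon 17. Of all 7-mers, 15.1% occur in the ERN1 coding sequence.

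**Figure D4:**
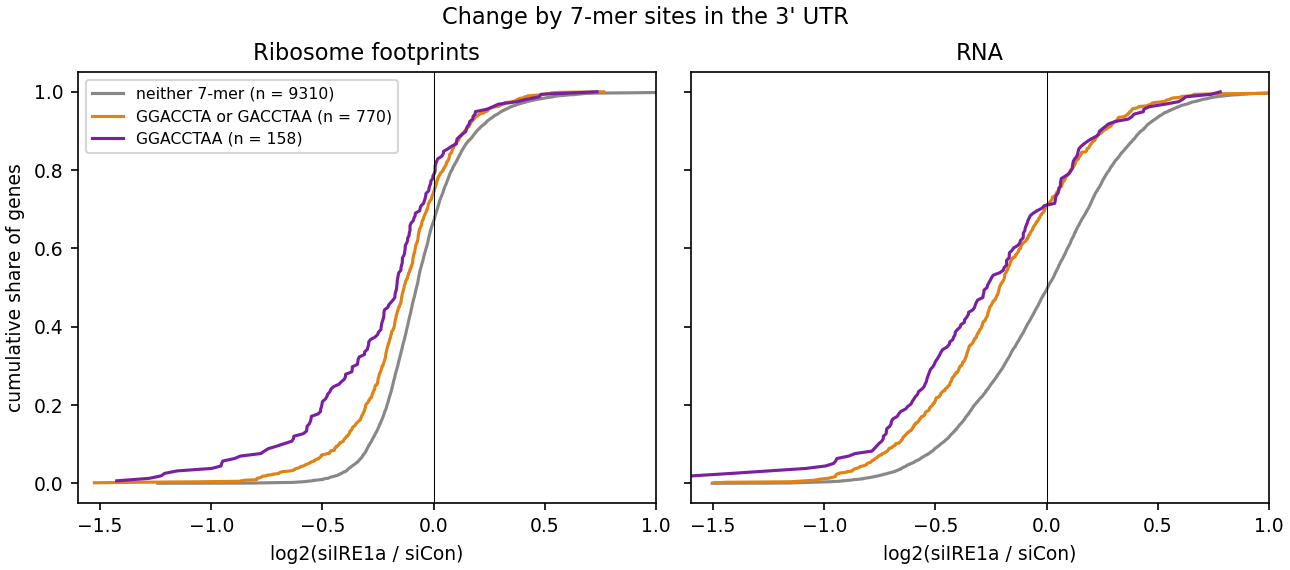
Cumulative share of genes (vertical) by log2 change of siIRE1a over siCon (horizontal) in footprints (left) and RNA (right), for genes with the 8-mer GGACCTAA in the 3′ UTR (158), with a 7-mer only (770) and with neither (9310). Genes with the 8-mer have the lowest medians, −0.17 in footprints and −0.27 in RNA, with 95% intervals that overlap those of genes with a 7-mer only.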

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

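Of 100 values recomputed for the main results, 60 stayed within 1.5 times the reported value or on the same side of the threshold. Removal of the GC trend and omission of genes with a seed 7-mer were chosen after seeing the data. No paired analysis was possible because the tables hold 1 value per group, and for the same reason a replicate left out, a replicate block, another tool, per-library TE models, other size factors, camera and fry were not run. The cause of a change was not tested except where fewer genes were counted.

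RNA genes at least 2-fold higher (4) and lower (11) became 36 and 49 with no filter, 0 and 1 at a mean of at least 10, and 0 and 1 with a pseudocount of 5, and the lower count became 2 with a pseudocount of 1. Footprint genes at least 2-fold higher (10) became 18 with no filter, 2 at a mean of at least 10 and 1 with a pseudocount of 5. Those at least 2-fold lower (8) became 1, 3 and 1 at a mean of at least 10 and with pseudocounts of 1 and 5, and 1 without genes with a seed 7-mer. TE rises (524) and falls (410) became 202 and 134 at an adjusted p under 0.01, 23 and 3 at an absolute log2 of at least 1, 173 and 233 at a mean of at least 1 in both assays, 10 and 46 at a mean of at least 10, and 50 and 59 with the GC trend removed, so that rises no longer outnumbered falls in the last 3 settings. Falls became 693 at an adjusted p under 0.1. The ERN1 RNA change (−0.72) became −0.35, −0.063 and −0.013 with pseudocounts of 0.1, 1 and 5, and its footprint change (−0.55) −0.14 and −0.034 with 1 and 5.

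The Fisher's exact adjusted p for lower TE of SRF genes (0.0168) became 1 with the GC trend removed, 0.0670 with median centring, 0.963 at an adjusted p under 0.01 and 0.0819 under 0.1. That of secreted and matrix proteins (0.00302) became 1, 0.120 and 1 in the first 3 of these settings. Removal of the GC trend gave 0.986 for higher TE of ER translocation genes and 0.0556 for lower TE of histones. The absence of rises among ribosomal protein genes (Fisher's exact adjusted p = 0.0848) passed at 0.0123 with an adjusted p under 0.1. Of the medians of the lists, 182 of 287 moved by little, and 149 of 210 values of named genes in RNA or footprints. Named TE genes stayed on the same side of the threshold in 27 of 44 cases.

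What depth limits is open for abundances, since the counts behind them are unknown. For TE, the back-calculated standard error had a median of 0.244 among the genes with the fewest footprints and 0.160 among those with the most.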

Other observations

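Gene families were grouped by symbol stem after the results had been seen, over 120 stems with at least 10 measured genes, and some stems share genes with the fixed lists. The tests of explanations were also chosen after the result was seen, except those of ribosomal protein genes against lists matched on abundance and coding length and of the members without a 7-mer, which were set before their outcome was known. All 14 measured PCDHB genes, the clustered beta protocadherins of cell adhesion, had higher footprints in siIRE1a cells, between 0.32 and 0.56 on the log2 scale with a median of 0.42, and higher RNA with a median of 0.46. Both medians ranked first among the 120 stems and lay above all random lists matched on abundance or on GC content. PCDHB2 footprints went from 3.42 to 4.28 and those of PCDHB11 from 2.27 to 3.09. These genes lie in 1 cluster and are similar in sequence, so shared reads and shared regulation are both open. Semaphorins (SEMA) had a median footprint change of 0.25, with 9 of 12 genes above 0 (percentile 99.99), at a low median footprint abundance of 0.391. Collagens (COL) had a median footprint change of 0.15 with 15 of 19 above 0 (percentile 99.99). COL6A1 is also a RIDD substrate, and COL1A1, COL3A1, COL4A1, COL4A2, COL5A1 and COL5A2 are among the secreted and matrix proteins. SEMA6A RNA went from 0.356 to 0.555 and its footprints from 0.882 to 1.19. SEMA3C RNA went from 0.672 to 0.496 and its footprints from 5.21 to 4.61.

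The SR splicing factors (SRSF) lay near the other end. All 11 had lower RNA, between −0.67 and −0.20 with a median of −0.38 (percentile 0.47, and 3.46 with GC matching), and their median footprint change was −0.24 with 2 of 11 above 0. SRSF3 footprints went from 106 to 84.0 and those of SRSF6 from 46.0 to 34.6, while SRSF8 went from 8.75 to 12.4. KLHL genes had a median RNA change of −0.41 over 22 genes with 6 above 0. KHDC1 was higher in both assays, by 1.11 in RNA and 1.06 in footprints, although its footprint values were 0.476 and 0.991.

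TE calls followed transcript GC content. A GC-dependent change in footprint abundance behind the pattern would need footprints to differ by at least 0.3 between the extreme GC groups. The difference was 0.0234 (95% interval 0.0089 to 0.034), which argues against it. Footprints per mRNA are the TE itself, so this value does not decide whether they changed. A GC-dependent difference between the RNA-seq libraries of the groups may account for the pattern: RNA change had a rho of 0.626 with GC content and footprint change one of −0.043. Lower RNA of AU-rich mRNAs in the cells with footprints kept would give the same values. Mitochondrially encoded mRNAs, which cytoplasmic mRNA regulation does not reach, were meant to separate these explanations. All 13 on the list were measured, but the minimum set for the test was higher, so it could not decide whatever the values. They had a rho of 0.714 in RNA and −0.269 in footprints, the direction that a library difference would give. On so few genes these explanations cannot be told apart. With 1 RNA value per group, no library could be checked on its own.

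Genes with GGACCTA in the 3′ UTR had lower footprints and RNA, and a candidate explanation is a seed match of the siRNA against IRE1α. With the 7-mer picked in a random part of the genes, the other 5119 genes gave a difference of −0.080 in footprints (95% interval −0.13 to −0.040) and of −0.18 in RNA, where gene sets matched on 3′ UTR length and GC content had a median change of −0.08 and genes with GGACCTA −0.19 (95% interval −0.25 to −0.11). In the same 5119 genes, base composition is argued against, since 95% of the other 594 7-mers of the same bases lay above −0.025 (the lowest was at −0.092). For footprints, 3′ UTR length and GC content are argued against too. Matched sets reached −0.094 at their lower bound and genes with GGACCTA −0.16 (95% interval −0.21 to −0.13). In RNA, 0% of the matched sets were as low as genes with GGACCTA (−0.19), which argues against 3′ UTR length and GC content there too. The RNA interval of these genes ended at −0.11, above the lower bound of matched sets (−0.13), so the stricter rule met by footprints was not met. The siRNA sequences are not stated in the labels, so the match with ERN1 cannot be checked, and 15.1% of all 7-mers occur in the ERN1 coding sequence. Of the 10 largest footprint decreases, 9 were in genes with a site, a count partly set by the choice of the 7-mers. These decreases may not depend on IRE1α.

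Footprints of ribosomal protein genes were lower, at a median of −0.336. A GC-dependent difference between RNA-seq libraries cannot enter footprints and is argued against by that value. A trend with abundance or coding length is argued against as the whole explanation by the lowest of 10000 matched lists (−0.239). These lists drew on the 20 nearest genes of each member, and how close these came in abundance was not checked. The matched lists had a median of −0.19, against −0.08 for all genes, so such a trend may account for part of the value. The 41 genes of the HIST stem, at a median footprint abundance of 184, also had a low median footprint change (−0.26). A seed match is argued against by the 57 members without either 7-mer (−0.338, 95% interval −0.37 to −0.32). Lower translation of TOP mRNAs may account for it but stays open: the footprints of the other TOP mRNAs were at percentile 0.40 of their matched lists, which was known before the test was chosen, and their TE in the authors' deposited table was at 48.5 (3.01 with GC matching). The median of ribosomal protein genes became −0.25 with median centring and −0.088 with quantile normalization, where it was still below all random lists. With quantile normalization other TOP mRNAs were at −0.087 and ribosome biogenesis genes at −0.17. A difference between the siRNA groups in footprint preparation or in the time of harvest after serum was not tested. Whether the lower footprints follow from IRE1α or from another effect of the siRNA is open, and with 1 value per group this needs replicates.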
